A study of Homo sapiens with 4 samples.

How the data were processed

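RNA from 4 samples of the SCC-15 cell line was analysed, 2 with REEP6 overexpression and 2 negative controls. Per the labels' protocols, cells were infected with lentivirus, harvested in Trizol and sequenced from libraries made with the NEBNext Ultra kit on an Illumina instrument. Groups and replicate numbers were taken from the sample titles.

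The authors deposited 1 table per sample with a raw count and an FPKM value for each of 51103 Ensembl genes. HISAT2 and HTSeq 0.13.5 on the genome build GRCh38 are named in the submitters' processing notes, with no roles. The gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so genes that overlap, lie antisense to each other or share reads with a paralog cannot be separated. Reads without a gene are not part of the tables used here. The counts were whole numbers that summed to 12856256, 15208629, 13236417 and 13302967, per the file headers raw counts. Deposited FPKM values were tested against the counts: dividing count by FPKM and by the library's total count gave 1 length per gene in all libraries, for 100% of 29161 genes with a count within a tolerance of 0.0001 (relative), so FPKM was scaled to the total of the count column. All 51103 identifiers were matched to GENCODE release 29 on GRCh38, and 51091 carried the same gene name there. Coordinates are from that annotation (1-based), and GC content is the length-weighted mean over a gene's transcripts.

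The design had assumed that the tables held FPKM only, with limma on log2(FPKM + 1) as the test. Because raw counts were present, a count test chosen after the files were opened was used instead. The planned limma test was kept as an alternative. Genes with an FPKM of at least 1 in at least 2 of the 4 libraries were tested (13077 genes). Counts were scaled by TMM (factors 1.01, 1.01, 0.986 and 0.995) and fitted with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood method with an abundance trend, 1 term for the group, all 4 libraries and 2 residual degrees of freedom. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 9.35%. The standard error of a log2 fold change was taken as its size over the square root of the quasi-likelihood F. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333, so none was used. FPKM is printed as mean ± SD over the 2 libraries of a group, and a positive log2 fold change means higher with REEP6.

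The rule for named genes, the gene lists and the main alternatives were fixed before the data were examined. REEP6 came first, then the 10 genes with the largest rise and the 10 with the largest fall on the log2(FPKM + 1) scale among called genes whose groups do not overlap, with a group mean of at least 2 FPKM and neither a clone name nor a pseudogene annotation. Up to 4 members with the smallest p were added from each of the 8 lists with the smallest camera p. Of the genes that this rule takes, 1 is not reported here. Genes outside this rule are named where a count was small or a feature was singled out, and were chosen after their values were seen. The 37 lists covered the endoplasmic reticulum, stress, growth, signalling, metabolism, immune and epithelial genes and markers of other cell types. Lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 31 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives.

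The method was tested on simulated data with the real means, library sizes and dispersion for 13077 genes, with 200 genes changed, as a stand-in for the comparison of REEP6 overexpression with the control. It recovered 43% of 100 genes changed 1.5-fold, 80% of 50 changed 2-fold and 96% of 50 changed 3-fold, with 15 false calls (10.3% of calls). With 1 of 31 lists shifted by 0.6 on the log2 scale, 1 list was called. The data had 3276 calls against 200 changed genes in the simulation, so these shares need not hold for the data.

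Alternatives chosen with that rule, applied to the count fit where they did not concern a pseudocount or quantile normalization, were pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5 FPKM, scaling to equal FPKM sums, median-of-ratios scaling, quantile normalization, scaling without the mitochondrially encoded genes, REEP6 and the 100 most abundant genes, no abundance trend, robust fitting, leaving out each library, the replicate number as a block, a 1.5-fold minimum and an adjusted p of 0.01. The planned limma test on log2(FPKM + 1) was also run. Alternatives added after seeing the data were DESeq2 1.42.0, edgeR's own filter, scaling by library totals and corrections for GC content or gene length. These corrections used a loess (span 0.3) of each library's deviations. Fits without 1 library and fits with the replicate block left 1 residual degree of freedom. Those without 1 library also assumed that a lone library varies like the other group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.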

Results

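Polyadenylated RNA was sequenced from SCC-15, a human cell line described as oral squamous cell carcinoma, after lentiviral overexpression of REEP6 (2 libraries) or with a negative control (2 libraries). REEP6 belongs to the receptor expression-enhancing protein family, membrane proteins of the endoplasmic reticulum, and variants of the gene are known in inherited retinal degeneration. The series set out to find genes and pathways that respond to REEP6. The libraries held 12856256 (control replicate 1), 15208629 (control replicate 2), 13236417 (REEP6 replicate 1) and 13302967 (REEP6 replicate 2) counts assigned to genes. Between 24021 and 24393 genes had a count in each. Libraries of one group differed by more than counting noise, with a chi-square per degree of freedom of 10.6 for the controls and 6.24 for the REEP6 pair, so each was used as a replicate. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

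With REEP6 overexpression, 8 of 12 measured interferon-response genes, 6 of 10 inflammatory genes and 6 of 10 extracellular matrix genes fell. By contrast, 10 of 13 mitochondrially encoded, 6 of 16 glycolytic and 8 of 17 fatty acid synthesis genes rose. Against these directions, 1 interferon-response gene rose and 2 fatty acid synthesis genes fell. Each of these lists passed a camera test with a preset correlation, and each had an adjusted p = 0.721 with an estimated correlation. The mitochondrial and glycolysis list calls ended after quantile normalization with limma, and fewer of their members passed with limma on log2(FPKM + 1). Interferon-induced IFIT2 fell 3.21-fold, the chemokine CXCL8 3.09-fold and the collagen COL7A1 2.31-fold, while the lactate exporter SLC16A3 rose 2.29-fold and the desaturase FADS2 1.91-fold (n = 2 per group). Larger single changes were also found. In polyadenylated RNA the histone gene HIST1H2AC rose 5.06-fold, and DIO2, the deiodinase that converts thyroxine to its active form, fell 9.61-fold. Of 13077 genes tested with edgeR's quasi-likelihood test, 3276 (25.1%) passed a Benjamini-Hochberg adjusted p of 0.05, of which 1422 were higher and 1854 lower with REEP6. Most changes were small, with a median absolute log2 fold change of 0.51 among the called genes, and 491 rose and 783 fell by at least 1.5-fold. With FPKM scaled to equal sums the edgeR split became 661 higher and 2824 lower (19.0% higher against 43.4%). That scaling shifted the median log2 fold change of all genes to -0.14. The limma test planned before the counts were seen called 1906 genes, 634 higher and 1272 lower.

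REEP6 itself was higher in both overexpression libraries than in both controls. REEP6 (ENSG00000115255, chromosome 19, 1490747 to 1497927, plus strand, GRCh38) had counts of 348 and 468 in the controls and 649 and 680 with overexpression. Its level was 11.8 ± 1.07 FPKM in the control and 20.4 ± 0.602 FPKM with overexpression (SD, n = 2), a log2 fold change of 0.82 ± 0.108 (SE) or 1.76-fold, with an edgeR adjusted p of 0.00119. By size of rise REEP6 ranked 209 among the 1422 genes that rose. The counts cover the whole gene, so endogenous and introduced transcripts were not separated.

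**Figure D1:**
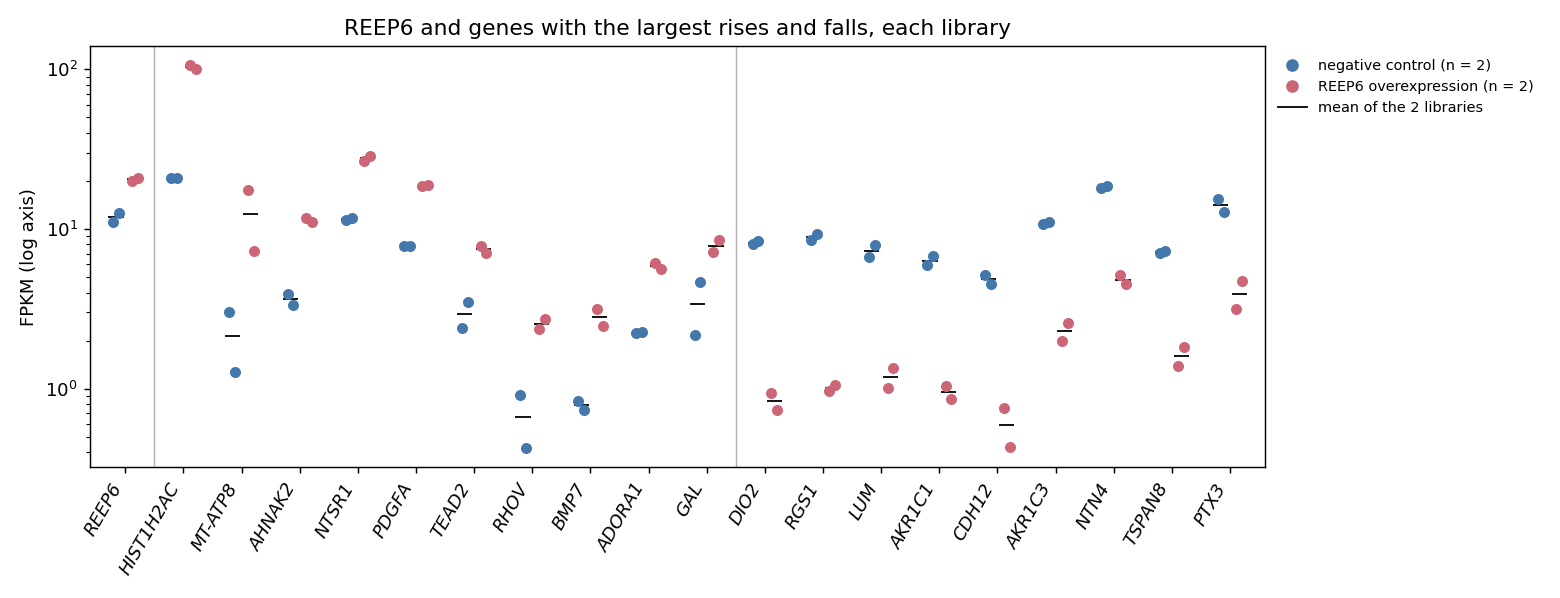
Expression of REEP6 (left), genes with the largest rises (middle) and genes with the largest falls (right) in FPKM on a log axis, one point per library and a line at the mean of the 2 libraries of a group. HIST1H2AC lies near 20.8 FPKM in the controls and 103 FPKM with REEP6, and DIO2 near 8.18 and 0.835 FPKM.

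Among the largest rises, HIST1H2AC (chromosome 6, 26124145 to 26139116), a histone H2A gene of a family with near-identical copies that can share reads, went from 20.8 ± 0.111 to 103 ± 4.26 FPKM (SD, n = 2; log2 fold change 2.34 ± 0.0927 SE, edgeR adjusted p 5.28e-06). Histone transcripts without a poly(A) tail would be missed in the polyadenylated RNA sequenced here. AHNAK2 (chromosome 14, 104937244 to 104978357), which codes for a very large PDZ-domain scaffold protein, rose 3.18-fold, from 3.65 ± 0.4 to 11.4 ± 0.392 FPKM. Genes for signalling proteins followed. The neurotensin receptor gene NTSR1 rose 2.46-fold, the adenosine A1 receptor gene ADORA1 2.64-fold, the growth factor gene PDGFA 2.44-fold and BMP7, a ligand of the TGF-beta family, 3.65-fold. TEAD2, a DNA-binding partner of YAP and TAZ, rose 2.55-fold. RHOV, a gene for an atypical small GTPase, rose 3.93-fold with a log2 fold change of 1.97, or 2.59 without control replicate 1. GAL, the galanin neuropeptide gene, rose 2.31-fold with a log2 fold change of 1.21, which was 0.78 without control replicate 1 and 1.92 without control replicate 2, and its call ended with limma on log2(FPKM + 1) (limma adjusted p 0.0675). MT-ATP8 had a log2 fold change of 2.58 ± 0.633 (SE) on counts of 8, 4, 48 and 20 in the order above. Its call ended without REEP6 replicate 1 (log2 fold change 1.80, edgeR adjusted p 0.119), the log2 fold change was 3.27 without control replicate 1, and the gene overlaps MT-ATP6, so its counts are uncertain.

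Among the largest falls, DIO2 (chromosome 14, 80197527 to 80387757) went from 8.18 ± 0.24 to 0.835 ± 0.145 FPKM (SD, n = 2; log2 fold change -3.26 ± 0.143 SE, edgeR adjusted p 6.91e-06). RGS1 (chromosome 1, 192575727 to 192580031), which shortens signalling by G protein alpha subunits, fell 8.62-fold, from 8.93 ± 0.532 to 1.02 ± 0.0611 FPKM. Lumican (LUM), a collagen-binding proteoglycan, fell 6.07-fold, and the cadherin gene CDH12 fell 7.98-fold. NTN4, a secreted netrin of basement membranes, fell 3.73-fold, the tetraspanin gene TSPAN8 4.41-fold and the pentraxin gene PTX3 3.50-fold. AKR1C1 fell 6.53-fold and AKR1C3 4.66-fold. These aldo-keto reductases act on steroids and are closely related paralogs, so the counting could divide their reads and the separate values are uncertain.

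Of the 37 gene lists 31 had at least 5 measured members, and 8 passed a camera test with a preset correlation at an adjusted p of 0.05. Members of 5 of these lists were higher on balance and members of 3 were lower. None of the 8 lists passed when camera estimated the correlation between genes from these 4 libraries, each at an adjusted p = 0.721. The estimate was below the preset 0.01 for the interferon (-0.0296), fatty acid (-0.0294) and inflammatory (0.00505) lists, and up to 0.89 for the others. Yet the unadjusted camera p of the interferon list went from 1.53e-05 to 0.0449. This variant tests on the 2 residual degrees of freedom, which leaves little power over 31 lists. A correlation above the preset thus did not end the interferon, fatty acid and inflammatory calls. For the other lists the estimate was above the preset, and the unadjusted camera p of the extracellular matrix list (0.89) went from 7.98e-05 to 0.303. There a higher correlation and the few degrees of freedom cannot be told apart.

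Interferon-response genes were lower with REEP6: of 12 measured members 8 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p 0.000237, adjusted p = 0.721 with an estimated correlation). IFIT2 went from 6.68 ± 0.214 to 2.04 ± 0.189 FPKM (SD, n = 2; log2 fold change -1.68 ± 0.154 SE, edgeR adjusted p 0.000256). IFI44 fell by 1.73 on the log2 scale, IFIT3 by 1.44 and DDX58, a sensor of viral RNA, by 1.04. The member that rose was OAS3, an oligoadenylate synthetase that activates RNase L (log2 fold change 0.68, chosen for mention after its value was seen), and with limma on log2(FPKM + 1) 0 members rose. Inflammatory and NF-kB target genes moved the same way, with 6 of 10 measured members lower and 0 higher, also adjusted over the list alone (camera adjusted p 0.00139, adjusted p = 0.721 with an estimated correlation). The neutrophil chemokine gene CXCL8 went from 5.82 ± 1.66 to 1.86 ± 0.134 FPKM (SD, n = 2; log2 fold change -1.63 ± 0.243 SE). NFKBIZ, an atypical inhibitor of NF-kB, fell by 1.05 on the log2 scale, NFKBIA, the inhibitor IkB-alpha, by 0.58 and TNFAIP2 by 0.47.

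Extracellular matrix genes were lower, with 6 of 10 measured members past the threshold and 7 adjusted over the list alone, all of them lower (camera adjusted p 0.000825, adjusted p = 0.721 with an estimated correlation). Without control replicate 1 or with a replicate block 1 member was higher. COL7A1, the anchoring fibril collagen, went from 61.7 ± 9.97 to 26.2 ± 2.36 FPKM (SD, n = 2; log2 fold change -1.21 ± 0.12 SE). Thrombospondin 1 (THBS1) fell by 0.90 on the log2 scale, COL6A1 by 0.89 and COL3A1 by 0.71. Of 10 fibroblast markers the 4 measured, namely LUM, POSTN, PDGFRB and COL3A1, were all lower with REEP6, also adjusted over the list alone, and COL3A1 belongs to both lists. POSTN was above the filter of 1 FPKM in the controls only. PDGFRA, a marker of the same list just below the filter, went the other way, with counts of 83 and 105 in the controls and 127 and 137 with REEP6, and was not tested in the main fit (chosen for mention after its values were seen). Endothelial and melanocyte markers had 0 measured members, and of the leukocyte markers 1 was measured and 0 were called. In the list of matrix metalloproteinases and plasminogen activation, 4 members were measured and 1 fell, the urokinase gene PLAU, by 1.52 on the log2 scale, while 2 fell without control replicate 1 or with a GC correction and 3 with equal FPKM sums or a replicate block.

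Mitochondrially encoded genes were higher, with 10 of 13 members past the threshold, also adjusted over the list alone, and 0 lower (camera adjusted p 0.000161, adjusted p = 0.721 with an estimated correlation). The complex I subunit gene MT-ND4L went from 758 ± 173 to 1425 ± 169 FPKM (SD, n = 2; log2 fold change 0.94 ± 0.143 SE). The ATP synthase subunit gene MT-ATP6 rose by 0.75 on the log2 scale, MT-ND5 by 0.59 and MT-ND3 by 0.52. The number past the threshold fell to 3 of 13 with limma on log2(FPKM + 1), MT-ND5 (limma adjusted p 0.0651) and MT-ND3 (0.0617) not among them, and to 6 of 13 with DESeq2. Nuclear copies of mitochondrial genes can share reads with all of them. The share of all counts from mitochondrially encoded genes was 3.90% and 5.44% in the controls and 5.81% and 6.02% with REEP6, so control replicate 2 lay close to the REEP6 libraries. The list call ended after quantile normalization with limma (camera adjusted p 0.549), where the most abundant genes are set to nearly equal values. Nuclear genes of oxidative phosphorylation had 5 of 17 members higher and 0 lower, also adjusted over the list alone, and their list did not pass (camera adjusted p 0.154). These counts depended on the setting: 3 were higher without REEP6 replicate 2 or with a GC correction, 0 were higher and 1 lower with equal FPKM sums (median log2 fold change -0.01), 0 passed with limma on log2(FPKM + 1), and 9 were higher and 1 lower with a replicate block.

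Glycolysis genes were higher, with 6 of 16 measured members past the threshold and 7 adjusted over the list alone (camera adjusted p 0.00119, adjusted p = 0.721 with an estimated correlation). SLC16A3, the monocarboxylate transporter that exports lactate, went from 2.41 ± 0.347 to 5.39 ± 0.671 FPKM (SD, n = 2; log2 fold change 1.19 ± 0.139 SE). Enolase 2 (ENO2) rose by 0.57 on the log2 scale, aldolase C (ALDOC) by 0.53 and GAPDH, a gene with many pseudogenes, by 0.44. With FPKM scaled to equal sums 2 members passed, GAPDH not among them (edgeR adjusted p 0.0505), with limma on log2(FPKM + 1) 2 passed, GAPDH (limma adjusted p 0.0573) and ENO2 (0.0515) not among them, and the list call ended after quantile normalization (camera adjusted p 0.153). The ENO2 call also ended without REEP6 replicate 2 (edgeR adjusted p 0.144) and with a GC correction (edgeR adjusted p 0.0867).

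Genes of fatty acid synthesis and lipid storage were higher on balance: of 17 measured, 8 rose, 2 fell and 7 were not called, or 9 rose and 2 fell adjusted over the list alone (camera adjusted p 0.00869, adjusted p = 0.721 with an estimated correlation). FADS2, the delta-6 desaturase of polyunsaturated fatty acids, went from 4.87 ± 0.547 to 9.16 ± 0.615 FPKM (SD, n = 2; log2 fold change 0.94 ± 0.106 SE). Fatty acid synthase (FASN) and stearoyl-CoA desaturase (SCD) each rose by 0.60 on the log2 scale. ACSL4, which activates arachidonic acid, fell by 0.87, and ELOVL6, an elongase of saturated fatty acids, fell by 0.50. With limma on log2(FPKM + 1) 5 members of the list rose and 2 fell, and with equal FPKM sums or a GC correction 6 rose and 2 fell. Cholesterol biosynthesis genes showed no such balance, with 2 of 19 higher and 3 lower, or 2 and 4 adjusted over the list alone (camera adjusted p 0.815).

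MAPK/ERK feedback and immediate early genes had 7 of 17 measured members higher and 1 lower, or 8 and 1 adjusted over the list alone (camera adjusted p 0.0157, adjusted p = 0.721 with an estimated correlation). The ERK feedback inhibitor genes SPRED2 (log2 fold change 0.63 ± 0.0866 SE) and SPRY2 (0.58 ± 0.104 SE) rose, as did the ETS factor gene ETV5 (0.48 ± 0.0813 SE) and the phosphatase gene DUSP4 (0.38 ± 0.0805 SE). JUN fell by 0.78 on the log2 scale, but 0 members were lower without control replicate 1. The list call ended without control replicate 1 (camera adjusted p 0.105), without REEP6 replicate 2 (0.0599), with no abundance trend (0.0553), with a GC correction (0.091) and after quantile normalization with limma (0.181). With limma on log2(FPKM + 1) 4 members were higher and 0 lower. With FPKM scaled to equal sums 3 were higher and 2 lower, and the DUSP4 call ended (edgeR adjusted p 0.0722).

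Ribosomal protein genes had 4 of 18 members higher and 0 lower, or 6 higher adjusted over the list alone (camera adjusted p 0.0254, adjusted p = 0.721 with an estimated correlation). RPL10 (log2 fold change 0.41 ± 0.101 SE), RPLP0 (0.33 ± 0.0959 SE), RPS18 (0.33 ± 0.0837 SE) and RPL13 (0.31 ± 0.101 SE) rose. Paralogous pseudogenes could take part of their reads, so these values are uncertain. With limma on log2(FPKM + 1) RPL10 (limma adjusted p 0.0818), RPS18 (0.0906), RPLP0 (0.121) and RPL13 (0.149) did not pass. Without REEP6 replicate 2, with a GC correction, or with FPKM scaled to equal sums, 0 members passed, and 2 passed without control replicate 1. The list call itself ended in 9 of 20 alternative settings, among them the GC correction (camera adjusted p 0.273), equal FPKM sums (0.122), the fit without control replicate 2 (0.0943) and the fit without REEP6 replicate 1 (0.157).

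**Figure D2:**
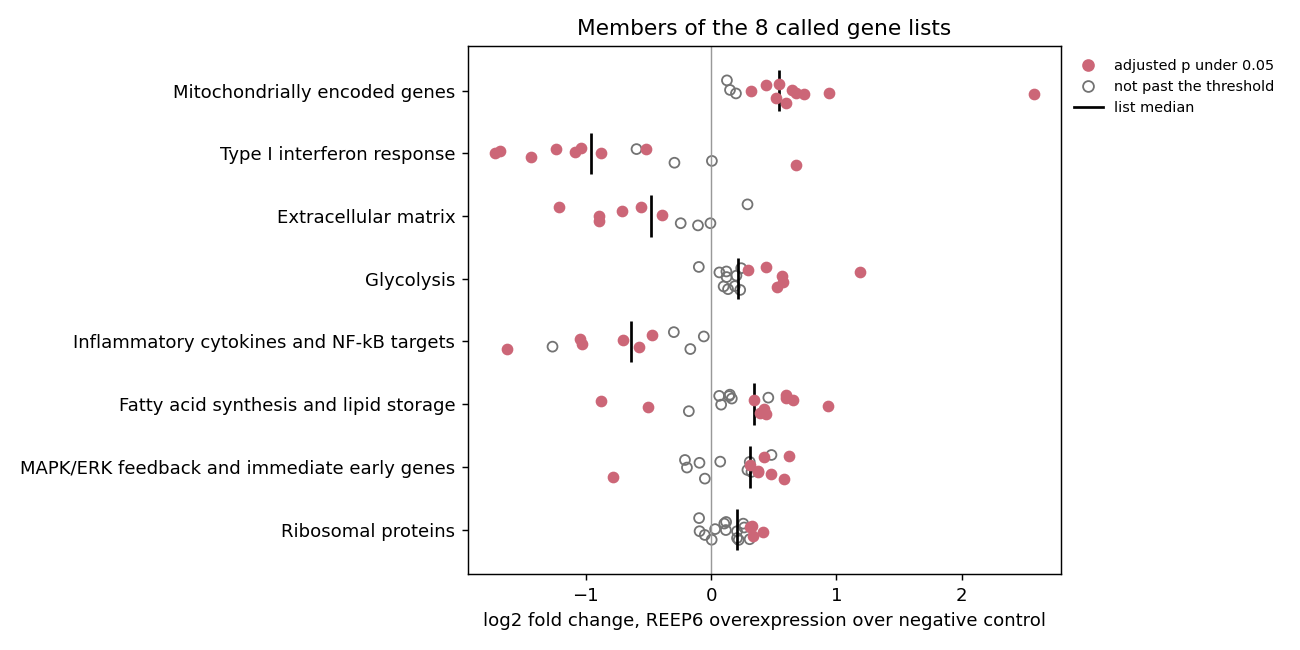
Log2 fold change of REEP6 overexpression over negative control for the measured members of the 8 gene lists that passed the camera test, one point per gene, filled where the edgeR adjusted p was under 0.05, with a line at the list median. The interferon-response median lies at -0.96 and the median of the mitochondrially encoded genes at 0.54.

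Genes of the endoplasmic reticulum, where REEP6 resides, moved in both directions, and neither of their lists passed. Among 15 measured ER-shaping genes REEP2 rose (log2 fold change 0.55) and REEP5 fell by 0.28 on the log2 scale, and 0 passed adjusted over the list alone (camera adjusted p 0.815). Without control replicate 1, 0 of these genes were higher and 3 lower, and 0 were called in either direction without any one of the other libraries, while a replicate block gave 3 higher and 7 lower. Among 17 chaperone and unfolded protein response genes 2 were higher and 3 lower, or 5 and 4 adjusted over the list alone (camera adjusted p 0.774), with 4 higher without control replicate 1, 0 higher without REEP6 replicate 1, and 9 higher and 4 lower with a replicate block. The largest falls among the called were SEL1L, by 0.73 on the log2 scale, and HSP90B1, by 0.61, both chosen for mention after their values were seen. Cell cycle and mitosis genes had 7 of 16 higher and 2 lower, also adjusted over the list alone (camera adjusted p 0.109). With a GC correction 7 were higher and 1 lower and the list passed (camera adjusted p 0.00582), while with equal FPKM sums 2 were higher and 3 lower (0.258), and 4 were higher without REEP6 replicate 1 or with limma on log2(FPKM + 1). TGF-beta targets had 3 of 15 higher and 7 lower, also adjusted over the list alone (camera adjusted p 0.213), among them the inhibitor of DNA binding genes ID1, ID2 and ID3, all lower. In the p53 target list 1 of 15 was higher and 5 lower, or 2 and 5 adjusted over the list alone (camera adjusted p 0.385), with 2 lower without control replicate 2 and without each REEP6 replicate.

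The other lists that were tested and not called also held members that passed in both directions or few that passed. The numbers higher and lower were 4 and 1 of 11 for the integrated stress response, 3 and 1 of 16 for DNA replication, 0 and 3 of 11 for autophagy and lysosome, and 3 and 1 of 11 for hypoxia. They were 1 and 5 of 14 for YAP/TAZ targets, 1 and 4 of 14 for NRF2 targets, 1 and 2 of 6 for Wnt targets, 2 and 2 of 7 for Notch targets, and 2 and 3 of 6 for ERBB receptors and ligands. They were 3 and 1 of 13 for epithelial-mesenchymal transition, 4 and 1 of 11 for the heat shock response, 1 and 1 of 10 for antigen presentation, 3 and 3 of 14 for apoptosis regulators, and 0 and 2 of 6 for cilium and photoreceptor genes. Adjusted over the list alone the numbers became 5 and 1 for the integrated stress response, 4 and 1 for DNA replication, 1 and 3 for autophagy and lysosome, 3 and 5 for YAP/TAZ targets, 2 and 4 for NRF2 targets, 2 and 2 for Wnt targets and 2 and 3 for Notch targets. They became 5 and 3 for epithelial-mesenchymal transition and 4 and 5 for the heat shock response, and were equal for hypoxia, ERBB receptors and ligands, antigen presentation, apoptosis regulators and cilium and photoreceptor genes. Leaving out 1 library moved at least 1 of these counts by over 1.5 times for 20 of the 23 lists that were tested and not called, and 0 of the 23 lists passed without 1 library. Such moves were found for 17 of the 23 with a GC correction, 16 with equal FPKM sums, 14 with a replicate block, 17 with limma on log2(FPKM + 1) and 7 with DESeq2, so these counts hold for the main fit only. With a GC correction 2 of the lists passed, cell cycle and autophagy and lysosome (camera adjusted p 0.0196, with 0 higher and 5 lower). Median and mean log2 fold change had opposite signs for NRF2 targets, ER chaperones, Wnt targets, Notch targets and apoptosis regulators.

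Most markers of squamous epithelium were low in every library. Of 53 genes in the lists for epithelial junctions, keratinocyte differentiation and basal keratinocytes, 37 were under 1 FPKM in all 4 libraries and 17 had no count at all. E-cadherin (CDH1) had 1 count in total, the basal keratin gene KRT5 had 4 and KRT14 had 6, and DSG3, IVL and KRT6A had 0. A total of 3 counts in the shallowest library corresponds to at most 0.387 FPKM for the 36 of these genes with a length, a limit that covers counting error only. Above 10 FPKM in every library were CD44, ITGA6, TJP1, ITGB4, DST and CLDN1. Among measured members of the basal keratinocyte list 4 of 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p 0.357), with 2 higher without control replicate 2 or without REEP6 replicate 1, and among epithelial junction genes 2 of 5 rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p 0.385). The keratinocyte differentiation list had 2 measured members of 22, of which 0 were called, or 1 as higher without REEP6 replicate 2 or with limma on log2(FPKM + 1). Vimentin (VIM), an intermediate filament protein of mesenchymal and many cultured cells, was abundant and rose, from 204 and 226 FPKM in the controls to 289 and 294 FPKM with REEP6 (log2 fold change 0.46, edgeR adjusted p 0.00572).

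**Figure D3:**
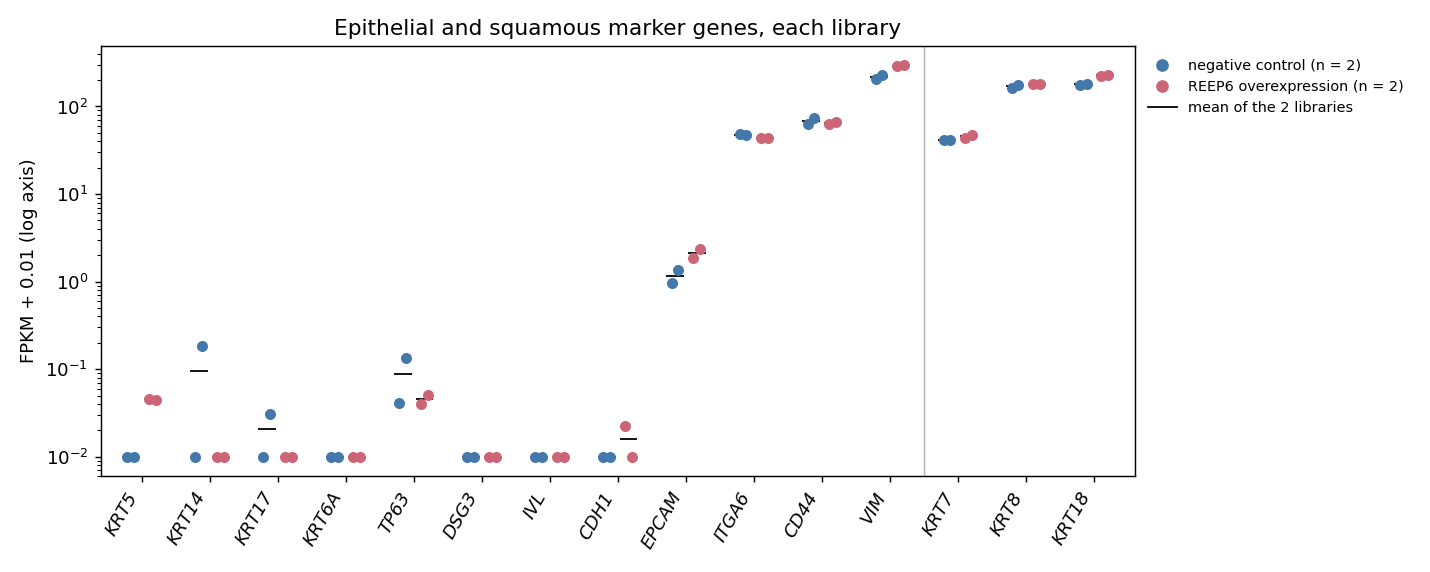
Expression of squamous and epithelial marker genes and VIM (left of the line) and of the simple epithelial keratin genes KRT7, KRT8 and KRT18 (right of it), as FPKM + 0.01 on a log axis, one point per library and a line at the mean of the 2 libraries of a group. The lowest value of KRT7, KRT8 and KRT18 is 41.0 FPKM, and the highest of CDH1 is 0.0122 FPKM.

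The direction of change followed the GC content of the genes. Genes that were higher had a median transcript GC content of 55.1%, genes that were lower 42.2%, and all tested genes 49.0%. In the decile of genes lowest in GC (25.1% to 39.5%) 6 rose and 460 fell, and in the highest decile (61.7% to 78.5%) 215 rose and 120 fell. Across genes, which are not independent replicates, log2 fold change and GC content had a Spearman correlation of 0.34. After a GC correction of each library 2296 genes were called, of which 1848 were among the 3276 and changed in the same direction. Gene length, as used for FPKM, had a weaker trend, with a Spearman correlation of -0.097 with log2 fold change and a median length of 4625 bases for genes that were higher, 6719 for genes that were lower and 4434 for all tested genes. After a length correction of each library 3145 genes were called, of which 2760 (84.2%) were among the 3276 and changed in the same direction, and the ribosomal list call ended (camera adjusted p 0.151). By class, 1371 protein-coding genes rose and 1727 fell of 10696 tested, and 42 long non-coding RNA genes rose and 87 fell of 1536.

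**Figure D4:**
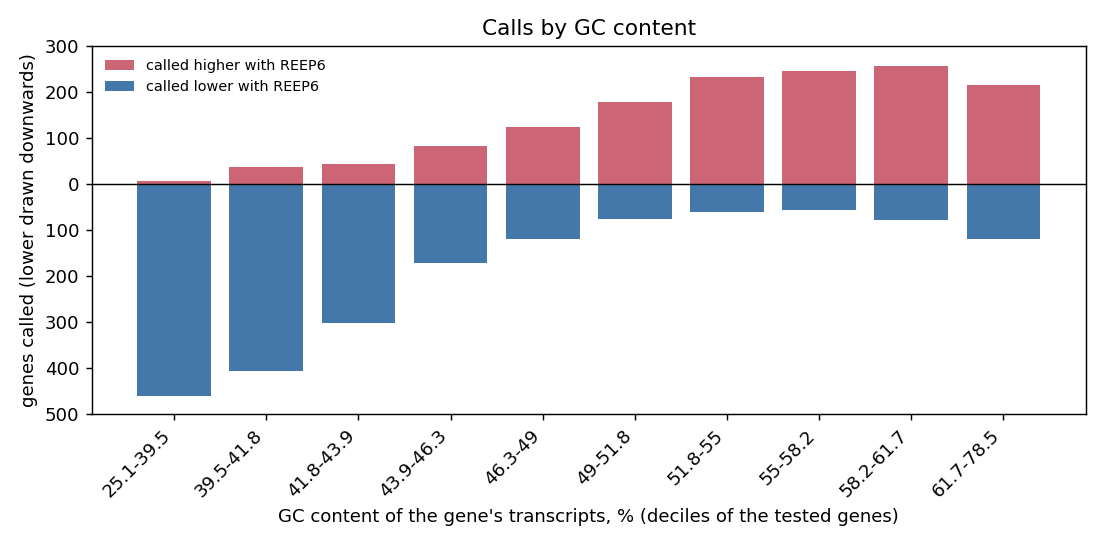
Number of genes called higher (upwards) and lower (downwards) with REEP6 overexpression in each decile of the tested genes, ordered by the GC content of their transcripts in percent. The lowest decile holds 6 genes called higher and 460 called lower, and the highest decile 215 and 120.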

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

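Limma on log2(FPKM + 1) was the planned test, and the edgeR count fit replaced it after raw counts were found in the files. DESeq2, edgeR's own filter, scaling by library totals and the GC and length corrections were chosen only after the result was seen. So were the counts of list members under the alternatives. REEP6 kept its rise and stayed past the threshold in all 22 alternatives, with log2 fold changes from 0.60 to 0.94 and adjusted p from 3.28e-16 to 0.0266, and from 0.73 to 0.94 with 1 library left out. The number of called genes, 3276 at first, was 1906 with limma on log2(FPKM + 1), 1830 and 1942 with pseudocounts of 0.1 and 5, and 1546 after quantile normalization, and the cause was not tested. The stricter criteria themselves lowered it to 1274 with a 1.5-fold minimum and to 1392 at an adjusted p of 0.01. With limma on log2(FPKM + 1) 33.3% of calls were higher. Leaving out 1 library gave 2212 to 3118 calls and 7 list calls each time. DESeq2 called 2561 genes, 2514 of them among the 3276, and gave no adjusted p for MT-ATP8. Of the 8 list calls 4 were left after quantile normalization, 1 with fry (interferon response, adjusted p 0.0149) and 0 with an estimated correlation, while other settings gave 6 to 12. Lists not called at first passed as well: 4 with no filter on low values (fibroblast, epithelial junction, cell cycle and nuclear oxidative phosphorylation genes, camera adjusted p 0.0112 to 0.0492), 2 with edgeR's own filter (fibroblast and epithelial junction genes, 0.0103 and 0.0116) and 2 with the GC correction (cell cycle, 0.00582, and autophagy, 0.0196), which ended the MAPK/ERK and ribosomal calls and so left 6 of the 8. Counts of list members moved over 1.5 times for 6 of the 8 lists with limma on log2(FPKM + 1) and for 4 with the replicate block. The interferon, extracellular matrix and fatty acid lists were called in all 20 settings tested by camera with the preset correlation, as was the inflammatory list except at the minimum of 5 FPKM, which left it too few members to test. Camera was not run for robust fitting or DESeq2. None of the 52 other genes taken by the rule for named genes changed direction in any of 1135 combinations of gene and setting. Calls were lost in 68 of them, 40 under limma, and 38 genes kept their call in every setting that tested them. The rule chose these genes by their change in the same libraries, and the groups of none of them overlap. A kept direction was therefore close to fixed in advance and a kept call was favoured, so neither is independent support. The stricter filter left fewer genes to test, and named genes under it have no value there.

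The libraries of the 2 groups share only a replicate number: the deviations of same-numbered libraries from their group means correlated at 0.271 over 2 pairs, across genes. With that number as a replicate block 6019 genes were called, all 3276 among them, and 5180 with a GC correction and the block together. The replicate block changed no list call. Fits with the block leave 1 residual degree of freedom. For REEP6 the SE was 0.108 in the main fit and 0.0956 with the block, while the edgeR adjusted p went from 0.00119 to 3.28e-16. Its SE thus changed little, so the lower p and the added calls were not read as a gain from pairing. The GC correction and the block together gave 11 list calls, 7 of them among the first 8: the ribosomal list was lost (camera adjusted p 0.179), and cell cycle (0.00403), autophagy (0.0114), TGF-beta (0.0142) and nuclear oxidative phosphorylation genes (0.0326) were gained. With 12856256 to 15208629 counts per library and 2 libraries per group, simulated 1.5-fold changes were recovered for 43% of genes, so a gene without a call may have changed by that much.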

Other observations

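The GC correction, the tests of the sizes of the calls before and after it and of squamous gene levels, and the secretory, histone and PPAR lists were chosen only after the result was seen, as were the genes named in these first paragraphs. Genes of the regulated secretory pathway were abundant in all libraries and several fell with REEP6. Of 17 measured genes of a list of secretory granule and neuropeptide genes, 8 were lower and 2 higher (camera p 0.0257 with the preset correlation, p = 0.138 with an estimated one). The granule protein gene SCG2 went from 367 to 180 FPKM (edgeR adjusted p 0.000202), SNAP25, which drives vesicle fusion, fell by 0.88 on the log2 scale, and the prohormone convertase gene PCSK1 by 0.56. The calcium sensor gene SYT1 fell by 1.23, and the carboxypeptidase and amidating enzyme genes CPE and PAM by 0.45 and 0.53. VGF, a granin-like precursor, stood at 300 and 283 FPKM and did not pass (edgeR adjusted p 0.665), while GAL and ENO2 were higher.

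Histone genes went both ways in the polyadenylated RNA that was sequenced, where transcripts without a poly(A) tail would be missed. Of 23 measured, HIST1H2AC and HIST2H2AC were higher, and HIST1H2BC, HIST1H1C, HIST1H2BK and HIST1H3E were lower (camera p 0.138, p = 0.295 with an estimated correlation), and reads shared between these similar genes make single values uncertain. Epidermal growth factor family genes parted as well: AREG, an EGFR ligand, fell by 2.39 on the log2 scale and ERBB2 rose by 0.87. The Notch receptor genes NOTCH1 and NOTCH3 rose by 1.16 and 1.11, while HEY1, a Notch target, fell by 0.99.

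The first pattern followed up is the GC trend of the calls. If uneven GC recovery between libraries had made all of them, a GC correction would have ended them, and 56.4% of the called genes were still called in the same direction. That share lay between the bounds of 50% and 67% set in advance, so that test was undecided. Over all 3276 called genes the median log2 fold change in the called direction went from 0.51 to 0.41, 80.3% of its size. The median SE was 0.105 before and 0.102 after. The smooth GC trend that was removed thus held only part of the change. A GC effect outside that trend would remain, so uneven recovery was not excluded for the calls that were left. For the 1428 calls that ended the median absolute log2 fold change went from 0.42 to 0.24, 58.2% of its size. Their median SE was 0.104 before and 0.10 after. These genes were chosen by their lost call, which by itself favours a smaller change, so the test does not decide whether GC recovery made these calls. Libraries of the same group also differed along GC, at up to 46.6% of the correlation seen between the groups, so a library effect and a real preference of the response for GC-rich genes cannot be told apart for this part.

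The second pattern is the rise of REEP6 after lentiviral overexpression, which was modest. The tests below ask whether something else raised REEP6, and why the rise was not larger was not tested. The GC trend does not account for the rise, since 88.1% of the REEP6 log2 fold change remained after the GC correction (0.72 ± 0.109 SE, edgeR adjusted p 0.00415). Nor does a change of the neighbourhood, because the 43 measured genes within 500 kb had a median log2 fold change of 0.066, with 7 higher and 6 lower. The introduced gene is a candidate explanation of the rise, as a hypothesis, and whether the vector's transcript was fully counted was not tested.

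The third pattern is the near absence of most squamous genes from cells labelled as oral squamous carcinoma. Counting failure of keratins is argued against by KRT7, KRT8 and KRT18, the lowest of which was at 41.0 FPKM in any library, and shallow sequencing by the 3-count limit, which was under 1 FPKM for 100% of the 36 genes with a count, whose length the FPKM values give. The 17 genes with no count have no such length, and by their longest annotated transcript their limit was at most 0.864 FPKM. Squamous lines usually express KRT5, KRT14, TP63 and E-cadherin, and CDH1 reached at most 0.012 FPKM here. The cells may have been another line, or SCC-15 cells that had lost squamous identity, and these cannot be told apart because no profile of SCC-15 was used here. Both groups share the pattern, so it does not separate them.

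A hypothesis on lipid metabolism was also tested. FABP4, a fatty acid carrier, fell from 1106 and 985 FPKM to 379 and 370 FPKM (log2 fold change -1.45), and it is a known target of PPAR transcription factors, so lower PPAR target transcription in general may be involved. Over 23 other measured PPAR targets the median log2 fold change was -0.145, with 9 lower and 1 higher (camera p 0.0195, p = 0.123 with an estimated correlation), between the bounds of -0.3 and -0.1 set in advance, so the test left it open. The lower genes included the fatty acid oxidation genes HADHA, HADHB, ACADM, ACADVL and ETFDH, and the higher one was ANGPTL4.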
